A study of Mus musculus with 30 samples.

How the data were processed

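Total RNA of CD4+ T cells, isolated by magnetic negative selection, and of CD11c+ cells, isolated with CD11c microbeads, was amplified, labelled with biotin and hybridised to Affymetrix mouse 430 PM arrays, per the labels. The deposited table holds 1 log2 value per probe set and array, which the authors made with RMA (background correction, quantile normalization and summary of probes), per the submitters' processing notes. The RMA version is not given in the sources used here. The 30 columns held values between 1.667 and 13.242, with column medians between 4.4555 and 4.544. Samples were grouped by their labels into 5 groups of 3 arrays for each of 2 cell types. The labels do not say that replicates are separate mice, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

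Of 45118 probe sets, 28898 had 1 gene symbol in the platform annotation, 551 had several and 15669 had none, and only those with 1 symbol were used. The Entrez IDs of 28689 matched the RefSeq gene table, and 0 symbols needed an update. Of 17097 genes, each was represented by its probe set with the highest mean over the 30 arrays. Genes above the array median on at least 3 of the 15 arrays of a cell type were tested, 10322 in CD4+ T cells and 10203 in CD11c+ cells.

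Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 values) over all 15 arrays of a cell type, which left 10 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and all tests were two-sided. For each cell type 7 comparisons were made. The difference between cell types was tested as an interaction over all 30 arrays and 10794 genes. A total of 33 gene lists, of pathways and of markers of the target and other cell types, were tested with camera of limma at a preset correlation of 0.01 where at least 3 members were tested, adjusted over the lists of a comparison. Of 308 such tests 160 were called, and 3 held with an estimated correlation, the erythroid list in the CD4+ comparisons of primed, tolerised and abatacept-treated with unimmunised mice. Not every called list is described. Members were counted over all genes tested and adjusted over the list alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

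The genes named were set by a rule. In each comparison they were, of the called genes whose arrays did not overlap between groups, the 8 largest rises and 8 largest falls. Added were at most 4 called members of each list, those with the smallest adjusted p, and all called genes of a comparison with 5 or fewer. Always named between abatacept and control IgG were 16 genes, of which Il21, Ido1 and Il6 did not pass the filter and were not tested. From this set the text mostly takes genes whose calls did not hang on 1 array, a choice made after the values were seen. The lists, the comparisons and their tests, this rule and the alternatives listed next were set before the data were examined. Some tests of explanations were chosen afterwards and are named below.

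The procedure was tested on simulated data for abatacept against control IgG. In CD4+ T cells (10322 genes) it recovered 52%, 90%, 98% and 88% of genes changed by 0.5, 1, 2 and -1 on the log2 scale, and 7.34% of 177 calls were false. In CD11c+ cells (10203 genes) it recovered 58%, 94%, 100% and 86%, and 5.06% of 178 calls were false. The alternatives set in advance were a fit on only the 2 groups compared, no filter, quantile normalization again, array weights, the replicate number as a block, the mean of all probe sets of a gene, leaving out each array in turn, and an estimated correlation in camera. Fits with the Eif2s3y or a salivary gene level (mean of Amy1 and Bpifa2) as a covariate, without the CD4+ unimmunised arrays, and on genes above the median in lymph node arrays were added after the data were seen. Scanner files were not used here.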

Results

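Gene expression was measured on 30 microarrays of cells from DO11.10 RAG2-/- mice on the BALB/c background. All T cells of these mice carry a transgenic receptor for a peptide of ovalbumin (OVA), because loss of RAG2 stops rearrangement of the mouse's own receptor genes. CD4+ T cells and CD11c+ cells, a fraction enriched for dendritic cells, were each profiled in 5 groups of 3 arrays. The groups were unimmunised mice, mice primed under the skin with 100 micrograms of OVA in complete Freund's adjuvant, primed mice given 10 mg/kg of control IgG, primed mice given 10 mg/kg of abatacept, and mice tolerised by OVA in the drinking water. Abatacept is a fusion of the outer part of CTLA-4 to an antibody tail, and it binds CD80 and CD86 and so blocks costimulation through CD28. Cells were taken 10 days after immunisation. CD4+ T cells came from axillary lymph nodes in the 3 primed groups, from mesenteric lymph nodes in the tolerised group, and from pooled lymph nodes and spleen in the unimmunised group, so tissue and treatment changed together in some CD4+ comparisons. CD11c+ cells came from pooled lymph nodes and spleen in all groups. Levels are log2 values given as mean ± SD of 3 arrays. The arrays of each gene named in a comparison did not overlap between its groups, except for Bcl6 and Cd80 under abatacept. Genes whose group mean lay below the array medians, which ran from 4.4555 to 4.544, were not shown to be above background there, so folds against such a mean are not exact. The number of arrays limits the precision of every comparison.

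The arrays of a group resembled each other closely, with correlations between 0.983 and 0.995 across all probe sets of the deposited table, which are not independent replicates. In CD4+ arrays the leading principal component held 66.9% of the variance and set the unimmunised arrays apart from the rest. In CD11c+ arrays it held 56.1%.

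**Figure D1:**
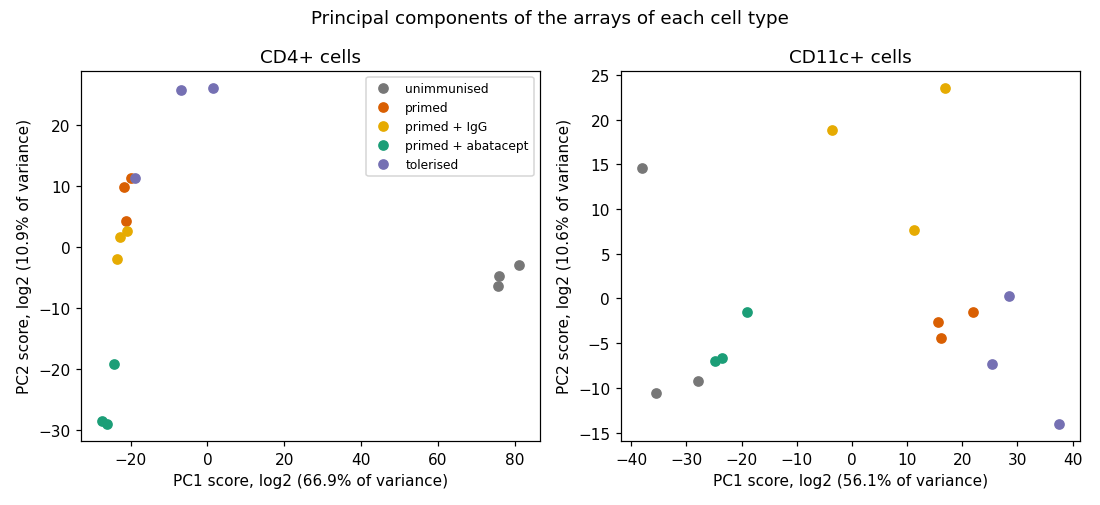
Principal components of the log2 values of the genes tested, with CD4+ arrays on the left and CD11c+ arrays on the right, where each point is 1 array coloured by group and each axis gives the share of variance in percent. The axes hold 66.9% and 10.9% of the variance in CD4+ arrays, and 56.1% and 10.6% in CD11c+ arrays.

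Sex-linked transcripts differed between groups, and the labels used here do not give the sex of the mice. The Y-linked gene Eif2s3y averaged 8.62 ± 0.18 in CD4+ primed, 8.89 ± 0.06 in CD4+ tolerised and 8.58 ± 0.05 in CD11c+ primed arrays (SD, n = 3). It averaged between 2.51 and 2.62 in the other groups, except in the CD11c+ control IgG arrays, which read 8.76, 5.92 and 8.20. Xist, which is transcribed from the inactive X chromosome, averaged 11.43 ± 0.08 in CD11c+ unimmunised and 4.5 ± 0.36 in CD11c+ primed arrays (SD, n = 3). In CD4+ primed arrays, where Eif2s3y was high, Xist also read 10.15 ± 0.80 (SD, n = 3), so transcripts typical of both sexes were present. Amy1, a salivary amylase gene, was high on some CD11c+ arrays. It read 5.23, 11.4 and 11.3 in the control IgG arrays, 12.1 in unimmunised replicate 2, 8.08 in tolerised replicate 3 and 7.69 in abatacept replicate 3.

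**Figure D2:**
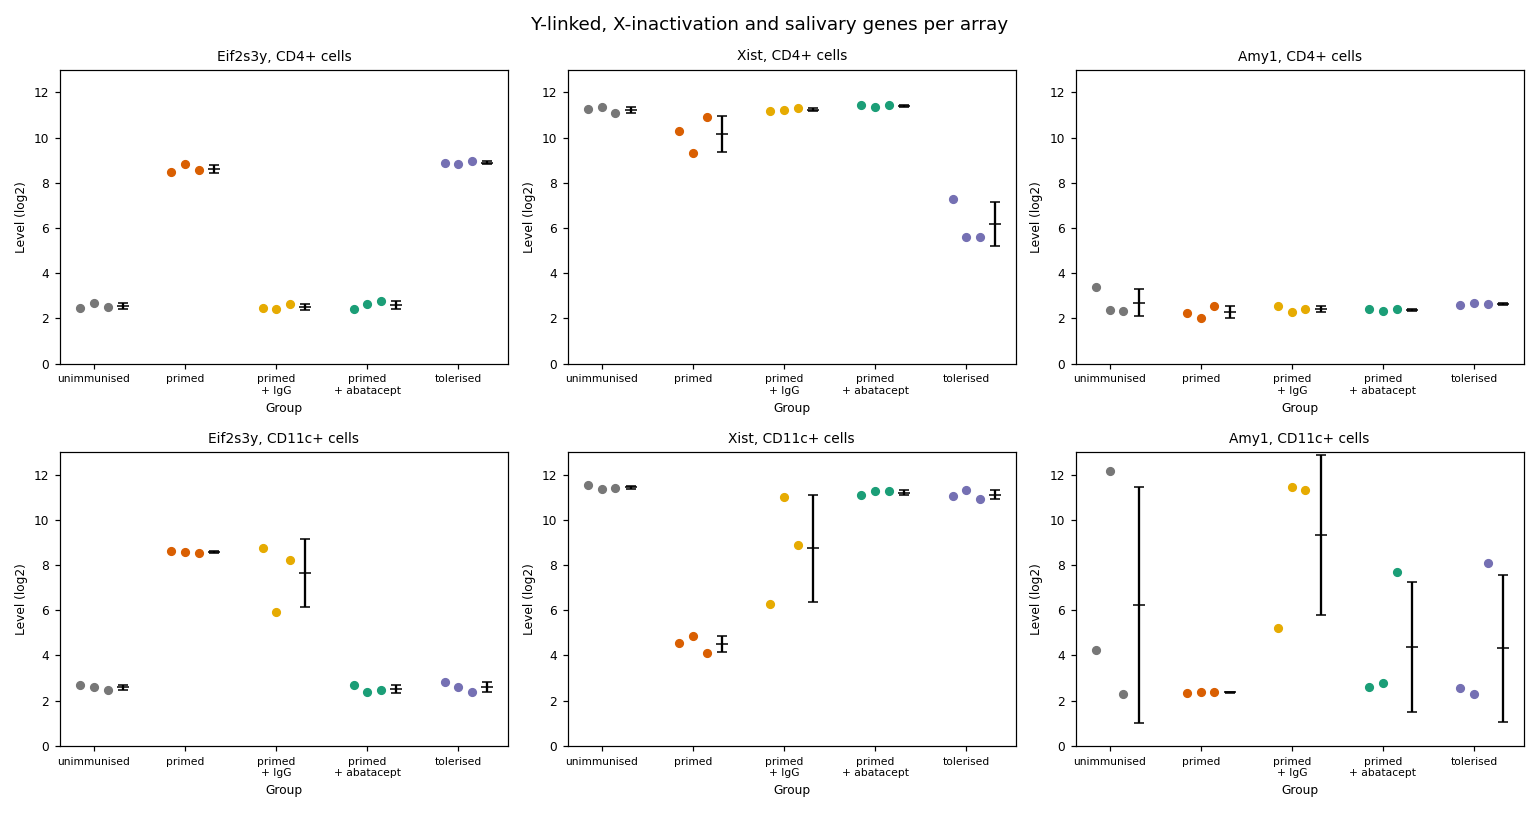
Log2 levels of Eif2s3y, Xist and Amy1 in CD4+ and CD11c+ arrays by group, where each point is 1 array and the black bar is the mean ± SD of 3 arrays. The CD11c+ control IgG arrays spread from 5.92 to 8.76 for Eif2s3y and from 5.23 to 11.4 for Amy1.

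Priming was first set against no immunisation, to see what immunisation with antigen did to CD4+ T cells. Genes of T cell activation rose. Icos, a costimulatory receptor of activated T cells, averaged 11.50 ± 0.10 in primed and 7.05 ± 0.06 in unimmunised arrays (SD, n = 3), a 21.9-fold rise (SE 0.13 log2, adjusted p = 2.2e-11). The inhibitory receptor Ctla4, below the array medians in unimmunised arrays, rose from 3.55 ± 0.05 to 8.97 ± 0.41 (SD, n = 3, adjusted p = 1.3e-10). Il2ra, the alpha chain of the interleukin-2 receptor, rose 15.9-fold, and the transcription factors Irf4 and Egr2, induced by receptor signalling, rose 6.93-fold and 5.99-fold. Izumo1r, the folate receptor 4 of regulatory and anergic T cells, rose 18.1-fold, and the cytokine gene Tnfsf11 (RANKL) rose from 3.35 ± 0.11 to 8.33 ± 0.38 (SD, n = 3). Of the 18 T cell activation genes tested, 14 rose and 2 fell, the growth regulator Myc and the inhibitory receptor Lag3 (named after its value was seen), with the same counts adjusted over the list alone (median log2 difference 1.98). By camera the list shifted with adjusted p = 1.6e-08, and with adjusted p = 0.081 with an estimated correlation. Of 11 T follicular helper genes 10 rose, adjusted over the list alone as well, among them Slamf6 and Tnfsf8 at log2 differences of 2.14 and 2.22 (list adjusted p = 1.3e-06, and adjusted p = 0.13 with an estimated correlation). Of 12 regulatory T cell genes 10 rose (median 2.05, adjusted p = 4.5e-06, and adjusted p = 0.15 with an estimated correlation), again 10 adjusted over the list alone. The chemokine receptor Cxcr3 of Th1 cells rose 6.03-fold, while 10 of 15 Th1 genes fell and 3 rose, also adjusted over the list alone, the fallen ones including the cytotoxic granule gene Nkg7 at -2.57 and the chemokine gene Ccl3 at -3.62, both also expressed by natural killer cells (list adjusted p = 0.031, and adjusted p = 0.26 with an estimated correlation). Cell cycle genes were lower in primed arrays: 15 of 30 fell and none rose, with the same counts adjusted over the list alone, including the replication factor Mcm7 at -0.87 and the kinase Cdk1 at -0.98 (adjusted p = 0.00054, and adjusted p = 0.44 with an estimated correlation).

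The CD4+ unimmunised arrays also held high levels of red cell, neutrophil and macrophage genes. Cell cycle genes, which any dividing cell expresses, averaged 8.34 in these arrays and 7.89 in primed arrays. Their fall is therefore not shown to have taken place in T cells. All 8 erythroid genes fell in primed arrays (median -6.06), including the red cell anion exchanger Slc4a1, from 10.61 ± 0.31 to 3.53 ± 0.65 (SD, n = 3, adjusted p = 1.1e-09). All 12 neutrophil genes fell (median -6.54), including the granule gene Camp, from 11.46 ± 0.19 to 4.23 ± 0.31 (SD, n = 3, adjusted p = 5e-12), and S100a8 at -8.04. All 12 monocyte and macrophage genes fell (median -3.98), as did all 6 of red pulp macrophages (median -5.09), with the iron exporter Slc40a1 at -7.64. Of 11 T cell genes 10 rose by a median of 1.06, with the receptor chain Cd3g going from 10.01 ± 0.03 to 11.09 ± 0.04 (SD, n = 3, adjusted p = 1.1e-08). All 5 mast cell and basophil genes fell (median -3.09), as did 7 of 8 dendritic cell and 5 of 6 natural killer cell genes, with 1 of each higher (medians -1.96 and -2.60), and these 3 lists had adjusted p = 0.00054, 0.0058 and 0.0038, and adjusted p = 0.17, 0.21 and 0.15 with an estimated correlation. These counts were the same adjusted over each list alone. The erythroid shift kept adjusted p = 0.0021 with an estimated correlation, while the neutrophil, macrophage, red pulp macrophage and T cell shifts had adjusted p = 0.055, 0.15, 0.076 and 0.055 with an estimated correlation. In all, limma called 4896 of 10322 genes, 2403 higher and 2493 lower, and 1363 of them differed at least 2-fold. The arrays of the groups did not overlap for 57.9% of genes, where chance gives 10%.

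**Figure D3:**
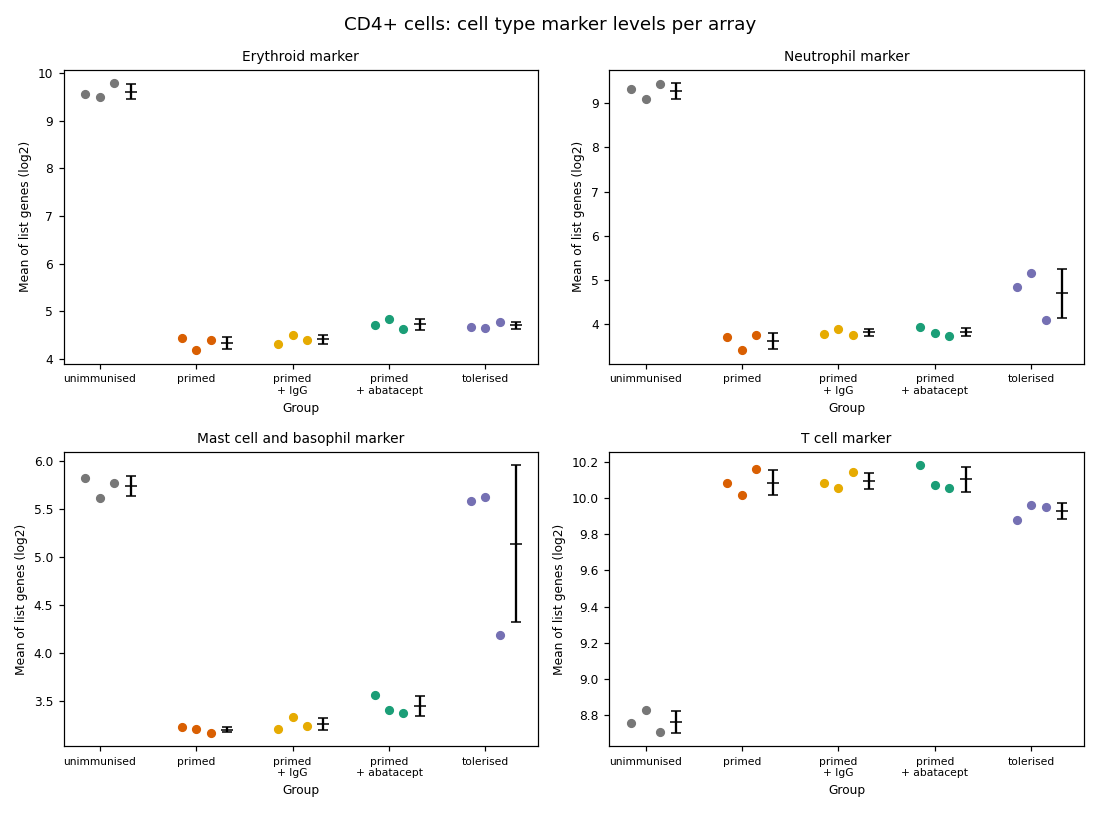
Mean log2 level of the erythroid, neutrophil, mast cell and basophil, and T cell marker lists in CD4+ arrays by group, where each point is 1 array and the black bar is the mean ± SD of 3 arrays. Erythroid genes averaged 9.61 in unimmunised and 4.34 in primed arrays, and mast cell and basophil genes averaged 5.14 in tolerised arrays.

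**Figure D4:**
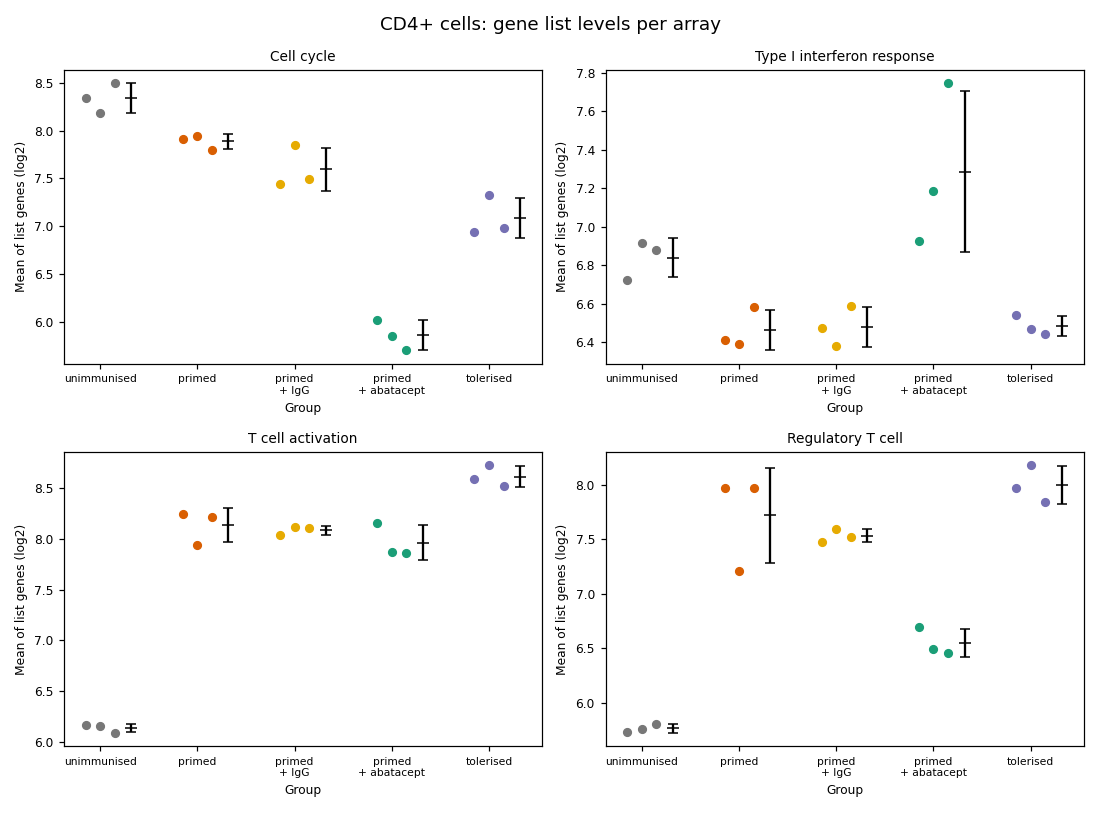
Mean log2 level of the cell cycle, type I interferon response, T cell activation and regulatory T cell lists in CD4+ arrays by group, where each point is 1 array and the black bar is the mean ± SD of 3 arrays. Cell cycle genes averaged 5.86 under abatacept and 7.60 under control IgG, and interferon response genes averaged 7.29 and 6.48.

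Tolerised mice were set against unimmunised mice in the same way, to see what oral antigen did. Ctla4 was higher in CD4+ T cells of tolerised mice, at 10.15 ± 0.20 against 3.55 ± 0.05 (SD, n = 3, adjusted p = 2e-11), with the unimmunised level below the array medians. Izumo1r was 39.5-fold higher, Egr2, which is needed for anergy, 14.5-fold, Icos 13.8-fold and the receptor-induced nuclear receptor gene Nr4a3 9.02-fold. Ccr9, the chemokine receptor for homing to the small intestine, rose 5.92-fold, from 6.21 ± 0.05 to 8.77 ± 0.24 (SD, n = 3, adjusted p = 1.2e-08), in cells from mesenteric nodes. Of 18 T cell activation genes 15 rose and 3 fell (median 2.32, adjusted p = 1.2e-10, and adjusted p = 0.072 with an estimated correlation). Of 19 anergy genes 15 rose and 1 fell, or 15 and 2 adjusted over the list alone (median 1.28, adjusted p = 1.1e-07, and adjusted p = 0.087 with an estimated correlation). Cell cycle genes fell, 29 of 30, with the cyclin Ccna2 at -1.75 and Cdk1 at -2.04 (median -1.26, adjusted p = 1.2e-10, and adjusted p = 0.20 with an estimated correlation). The other-cell transcripts of the unimmunised arrays stood out here too: all 8 erythroid genes fell (median -5.25, adjusted p = 0.0041 with an estimated correlation) and all 12 neutrophil genes fell (median -4.30, adjusted p = 0.076 with an estimated correlation). Of 12 macrophage genes 10 fell, all 6 red pulp macrophage genes fell and 9 of 11 T cell genes rose (medians -3.03, -3.97 and 0.95), with adjusted p = 5.6e-06, 5.6e-06 and 1.2e-07, and adjusted p = 0.20, 0.087 and 0.072 with an estimated correlation. Adjusted over the list alone, the counts for the activation, cell cycle and other-cell lists were the same. The rises of activation and anergy genes were not tested apart from the rise of T cell genes. In total limma called 5114 of 10322 genes, 2093 higher and 3021 lower (2623 and 2684 when quantile normalized again), and arrays did not overlap for 56.1% of genes against 10% by chance.

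Tolerised and primed CD4+ T cells were then compared directly, as 2 outcomes of exposure to the same antigen. The inhibitory receptor Lag3 was 5.66-fold higher in tolerised arrays, at 6.50 ± 0.52 against 3.99 ± 0.38 (SD, n = 3, SE 0.25 log2, adjusted p = 3.4e-05). Also higher were Ctla4 by 2.27-fold, Egr2 by 2.42-fold, Nr4a3 by 3.46-fold and the costimulatory receptor Tnfrsf9 (4-1BB) by 4.32-fold. Nt5e (CD73), the ectoenzyme that makes adenosine, rose from 4.25 ± 0.32 to 5.96 ± 0.17 (SD, n = 3, adjusted p = 2.3e-05). Of 18 activation genes 9 rose and 2 fell, or 10 and 4 adjusted over the list alone (adjusted p = 0.00034, and adjusted p = 0.20 with an estimated correlation). Immediate early genes, which also respond to handling of cells, rose as well, 5 of 12 with 1 lower, also adjusted over the list alone (median 0.21, adjusted p = 0.0040, and adjusted p = 0.20 with an estimated correlation). Lower were Cd40lg, the ligand by which T cells help B cells, by 3.66-fold (adjusted p = 1.8e-05), Icos by a log2 difference of -0.67, and S1pr1, the receptor for leaving lymph nodes, at -0.88. Ccr9 and the integrin chain Itga4 were 5.02-fold and 3.68-fold higher, while Itgb7, the partner of Itga4 in the gut homing integrin, was lower at -0.57. The gut homing list of 5 did not pass its test, with 2 higher and 1 lower, also adjusted over the list alone (median 0.26, adjusted p = 0.073). Of 19 anergy genes 11 rose and 2 fell, or 13 and 2 adjusted over the list alone (median 0.41, adjusted p = 3.3e-08, and adjusted p = 0.13 with an estimated correlation). Of 15 Th1 genes 8 rose and 1 fell, or 9 and 2 adjusted over the list alone, including the T-box factor Eomes by 4.54-fold and the cytokine Ifng by 3.33-fold (adjusted p = 5.5e-06, and adjusted p = 0.13 with an estimated correlation). Natural killer cell genes, a cell type that also expresses Eomes and Ifng, rose too, 3 of 6, or 3 with 1 lower adjusted over the list alone (median 0.66, adjusted p = 0.0047, and adjusted p = 0.15 with an estimated correlation). Cell cycle genes fell, 22 of 30, or 27 adjusted over the list alone (median -0.92, adjusted p = 5.3e-15, and adjusted p = 0.15 with an estimated correlation). Regulatory T cell genes were split, 4 higher and 2 lower of 12, or 6 and 4 adjusted over the list alone (adjusted p = 0.034, and adjusted p = 0.45 with an estimated correlation). Hic1, a transcriptional repressor of intestinal lymphocytes, rose 15.8-fold. Genes of other cells were also higher in tolerised arrays. All 5 mast cell and basophil genes rose, also adjusted over the list alone (median 2.57, adjusted p = 3.9e-07, and adjusted p = 0.13 with an estimated correlation), with the carboxypeptidase Cpa3 at 7.27 ± 0.88 against 3.48 ± 0.15 (SD, n = 3, adjusted p = 2.7e-05). Dendritic cell, macrophage, red pulp macrophage and neutrophil lists rose by medians of 0.88, 0.66, 0.95 and 0.63, with 4 of 8, 4 of 12, 5 of 6 and 4 of 12 genes higher and 1 macrophage gene lower. Adjusted over the list alone the higher counts were 4, 6, 5 and 8. Their adjusted p = 0.00078, 0.00026, 2.3e-05 and 3.3e-06, and adjusted p = 0.15, 0.28, 0.15 and 0.15 with an estimated correlation. The B cell list of 3 genes also shifted higher, 1 of them called, or 2 adjusted over the list alone (median 0.36, adjusted p = 0.023, and adjusted p = 0.15 with an estimated correlation). The macrophage lysozyme gene Lyz2 and the cytotoxic granule gene Gzma were higher by 2.99 and 3.89. The T cell gene Trat1 fell by 2.08, while of the T cell marker list none other fell and none rose (adjusted p = 0.77). In this comparison limma called 1514 of 10322 genes, 644 higher and 870 lower, 30.5% of genes did not overlap against 10% by chance, and 984 genes were called without tolerised replicate 1. The excess of lower genes did not hold, with 700 higher and 704 lower when quantile normalized again and 788 and 779 without tolerised replicate 3. With only the arrays of the 2 groups in the fit, 822 genes were called, and tissue of origin differed between the groups.

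Abatacept was compared with control IgG in primed mice, to see what costimulation blockade did to the primed T cells. Genes of cell division fell. Ccna2 averaged 5.84 ± 0.16 under abatacept and 8.56 ± 0.25 under control IgG (SD, n = 3), a 6.6-fold fall (SE 0.14 log2, adjusted p = 6.9e-08). Rrm2, a subunit of the enzyme that makes deoxynucleotides, fell 6.66-fold, the mitotic survival factor Birc5 6.36-fold and Cdk1 5.31-fold. Of 30 cell cycle genes 29 fell, 29 also adjusted over the list alone (median -1.94, adjusted p = 1.9e-29, and adjusted p = 0.083 with an estimated correlation). Among activation genes, Icos fell 3.7-fold, from 11.34 ± 0.19 to 9.45 ± 0.30 (SD, n = 3, adjusted p = 7.7e-07), and Il2ra fell 4.6-fold, from 8.95 ± 0.16 to 6.75 ± 0.09 (SD, n = 3, adjusted p = 2.3e-06). The costimulatory receptor Tnfrsf4 (OX40) and the factor Batf fell by 1.24 and 1.13. The receptor-induced genes Nr4a1, Nr4a3 and Egr2 rose instead, by 1.46, 1.46 and 0.82. The activation list as a whole had 6 higher and 5 lower of 18, or 6 and 7 adjusted over the list alone, and did not pass its test (median 0.18, mean -0.12, adjusted p = 0.46). Foxp3, the factor that defines regulatory T cells, fell 3.35-fold, from 8.60 ± 0.40 to 6.86 ± 0.09 (SD, n = 3, adjusted p = 0.0059), as did Ebi3, a subunit of interleukin-35, by 6.12-fold. Of 12 regulatory T cell genes 6 fell and none rose, or 8 and none adjusted over the list alone (median -1.28, adjusted p = 0.0014, and adjusted p = 0.33 with an estimated correlation). Cxcr3 fell 9.26-fold (adjusted p = 1.2e-07), and the protease gene Gzmb and the T helper factor Maf fell by 2.08 and 1.67, while the chemokine gene Ccl5 rose 4.91-fold, so that of 15 Th1 genes 7 fell and 3 rose, also adjusted over the list alone (list adjusted p = 0.71). Ctla4 read 9.44 ± 0.35 under abatacept and 9.02 ± 0.13 under control IgG (SD, n = 3, adjusted p = 0.16), Ifng 4.53 ± 0.23 and 3.94 ± 0.40 (SD, n = 3, adjusted p = 0.14), and none of these passed the test, nor did Bcl6, the factor of follicular helper cells (log2 difference 0.12, adjusted p = 0.58), whose sign turned to -0.030 without abatacept replicate 1. Cd28 was higher by 0.30 (adjusted p = 0.040), a call lost without abatacept replicate 1, 2 or 3 (adjusted p = 0.095, 0.065 and 0.096) or control IgG replicate 1 or 2 (adjusted p = 0.15 and 0.083).

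Several other gene groups moved under abatacept in CD4+ T cells. Type I interferon response genes rose, 13 of 20, or 16 adjusted over the list alone (median 0.71, adjusted p = 1.4e-14, and adjusted p = 0.13 with an estimated correlation). The interferon-induced genes Ifit1 and Ifit3 rose 3.7-fold and 3.95-fold, with Ifit1 at 9.49 ± 0.73 against 7.60 ± 0.12 (SD, n = 3, adjusted p = 0.0004), and the interferon regulatory factor Irf7 rose by 1.03. Genes of naive T cells rose, 3 of 9, or 5 adjusted over the list alone, namely the transcription factors Bach2, Klf2 and Lef1 by 0.63, 0.46 and 0.41 (list adjusted p = 4.7e-05, and adjusted p = 0.083 with an estimated correlation). Glycolysis genes fell, 7 of 13, or 10 adjusted over the list alone, with the triose phosphate isomerase gene Tpi1 down 2.3-fold (list median -0.27, adjusted p = 0.00053, and adjusted p = 0.20 with an estimated correlation). Cholesterol synthesis genes fell, 7 of 13, or 10 adjusted over the list alone, with squalene epoxidase Sqle down 2.72-fold and the sterol sensor Insig1 1.94-fold (list median -0.48, adjusted p = 0.00019, and adjusted p = 0.20 with an estimated correlation). Immediate early genes rose, 5 of 12, or 7 adjusted over the list alone, with Fos up 4.81-fold, Jun by 1.55 and the phosphatase Dusp1 from 8.86 ± 0.12 to 10.45 ± 0.22 (SD, n = 3) (list adjusted p = 2.8e-07, and adjusted p = 0.083 with an estimated correlation). The inflammatory caspase gene Casp1 fell 7.88-fold and the interleukin-1 receptor Il1r1 5.69-fold. Markers of natural killer cells were higher, 2 of 6 tested, also adjusted over the list alone (median 0.50, adjusted p = 0.0012, and adjusted p = 0.14 with an estimated correlation), with the receptor Klra9 at 6.42 ± 0.27 against 2.94 ± 0.38 (SD, n = 3, adjusted p = 0.00018) and the adaptor Tyrobp up by 2.80. Erythroid, neutrophil and mast cell lists did not pass the test (adjusted p = 0.088, 0.28 and 0.45). Of 10322 genes limma called 1722, 344 higher and 1378 lower, with 293 differing at least 2-fold, and 36.7% did not overlap against 10% by chance. Without abatacept replicate 2 or 3 or control IgG replicate 2 the count was 1074, 1031 or 1107.

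Control IgG was compared with priming alone, as a check of the antibody control. In CD4+ T cells limma called 9 of 10322 genes, all lower under control IgG, with 873 genes at an unadjusted p under 0.05, and 17.9% of genes did not overlap against 10% by chance. On the Y chromosome lie at least 6 of the 9, Eif2s3y, Kdm5d, Uty, Ssty1, Ssty2 and Orly, led by Eif2s3y at 2.51 ± 0.12 against 8.62 ± 0.18 (SD, n = 3, adjusted p = 7.8e-13), and the others were Astx6, Ccl5 and Jun. The Astx6 call (adjusted p = 0.021) was lost without any 1 of the 6 arrays, with adjusted p between 0.065 and 0.15. Ccl5 fell by 1.67 (adjusted p = 0.019), a call lost without control IgG replicate 1 or primed replicate 1 or 2 (adjusted p = 0.080, 0.10 and 0.14). Jun fell by 0.93 (adjusted p = 0.019), a call lost without control IgG replicate 2 or 3 or any primed replicate, with adjusted p between 0.077 and 0.10. Cell cycle genes shifted lower as a list (median -0.30, adjusted p = 5e-09, and adjusted p = 0.61 with an estimated correlation), although no member was called over all genes or adjusted over the list alone. Glycolysis, Th17 and immediate early lists also shifted lower (medians -0.16, -0.31 and -0.087), with adjusted p = 0.00065, 0.014 and 0.023, and adjusted p = 0.57, 0.57 and 0.61 with an estimated correlation. Of their genes only Jun was called, and adjusted over the list alone Jun and 2 of 6 Th17 genes.

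CD4+ T cells of abatacept-treated primed mice were also set against those of tolerised mice, to see whether blockade and oral tolerance left like profiles. Activation and regulatory genes were lower under abatacept. Of 18 activation genes 10 fell and 1 rose, or 12 and 1 adjusted over the list alone (median -0.58, adjusted p = 0.0012, and adjusted p = 0.25 with an estimated correlation). Tnfrsf4 fell from 7.64 ± 0.10 to 5.32 ± 0.15 (SD, n = 3, adjusted p = 1.4e-06), and the inhibitory receptor Pdcd1 (PD-1) from 6.01 ± 0.45 to 4.03 ± 0.12 (SD, n = 3, adjusted p = 1.5e-05). Cxcr3 fell 9.49-fold, and the Th1 factor Tbx21 and the Th17-associated receptor Ccr6 fell by 1.77 and 2.24. Of 12 regulatory T cell genes 11 fell, the same number adjusted over the list alone, with Klrg1, a receptor of terminally differentiated cells, at -2.85 (list median -1.51, adjusted p = 7.2e-09, and adjusted p = 0.13 with an estimated correlation). Of 15 Th1 genes 11 fell, also adjusted over the list alone (adjusted p = 1.9e-05, and adjusted p = 0.13 with an estimated correlation). Of 30 cell cycle genes 27 fell, or 29 adjusted over the list alone (median -1.24, adjusted p = 6e-18, and adjusted p = 0.14 with an estimated correlation). Genes of naive T cells were higher, 6 of 9, or 7 adjusted over the list alone, with S1pr1 and Klf2 up by 1.15 and 0.76 (adjusted p = 2.8e-06, and adjusted p = 0.057 with an estimated correlation). Interferon response genes were higher, 14 of 20, or 15 adjusted over the list alone (median 0.78, adjusted p = 5.1e-10, and adjusted p = 0.16 with an estimated correlation), with Ifit1 up 5.65-fold. All 5 mast cell and basophil genes were lower under abatacept, also adjusted over the list alone (adjusted p = 0.00031, and adjusted p = 0.16 with an estimated correlation), as were Lyz2 at -3.78 and the Y-linked Eif2s3y at -6.29. Dendritic cell, macrophage, red pulp macrophage and neutrophil genes were lower too, 5 of 8, 7 of 12, 5 of 6 and 3 of 12, or 5, 9, 5 and 6 adjusted over the list alone (medians -0.85, -0.98, -0.89 and -0.57). Those lists had adjusted p = 0.036, 0.0044, 0.0032 and 0.015, and adjusted p = 0.34, 0.37, 0.25 and 0.37 with an estimated correlation. T cell genes were higher, 3 of 11, or 5 with 1 lower adjusted over the list alone (median 0.11, adjusted p = 0.013, and adjusted p = 0.28 with an estimated correlation). In this comparison limma called 2408 of 10322 genes, 778 higher and 1630 lower, and 34.5% did not overlap against 10% by chance. With only the arrays of the 2 groups in the fit, 1107 were called, and the lymph nodes differed between the groups.

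Set against unimmunised mice, CD4+ T cells of abatacept-treated primed mice differed in activation genes. Ctla4 was higher, at 9.44 ± 0.35 against 3.55 ± 0.05 (SD, n = 3, adjusted p = 6.8e-11), Egr2 was 10.7-fold and Icos 5.3-fold higher, and Bach2 was higher by 1.45. Immediate early genes were higher, 7 of 12 with 3 lower, also adjusted over the list alone (median 0.49, adjusted p = 0.022, and adjusted p = 0.28 with an estimated correlation). Of 18 activation genes 16 rose and 2 fell, with the same counts adjusted over the list alone (median 1.62, adjusted p = 6.2e-09, and adjusted p = 0.10 with an estimated correlation). Cell cycle genes were lower, 29 of 30, also adjusted over the list alone, with Ccna2 down 13.4-fold (list median -2.68, adjusted p = 1.1e-14, and adjusted p = 0.15 with an estimated correlation). The other-cell transcripts of the unimmunised arrays again differed, with all 8 erythroid genes lower, also adjusted over the list alone (median -5.40, adjusted p = 0.010 with an estimated correlation). All 12 neutrophil, 12 macrophage, 6 red pulp macrophage and 5 mast cell and basophil genes were lower (medians -6.34, -4.38, -5.09 and -2.74), with adjusted p = 0.10, 0.16, 0.11 and 0.28 with an estimated correlation. Lower were also 7 of 8 dendritic cell and 5 of 6 natural killer cell genes, with 1 of each higher (adjusted p = 0.042 and 0.045, and adjusted p = 0.32 and 0.28 with an estimated correlation). All 11 T cell genes were higher (median 1.08, adjusted p = 5e-09, and adjusted p = 0.056 with an estimated correlation), and these 7 counts were the same adjusted over the list alone. Of 10322 genes limma called 5978, 2415 higher and 3563 lower (3012 and 3175 when quantile normalized again), and 64.2% did not overlap against 10% by chance.

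In CD11c+ cells, priming was set against no immunisation to see what the antigen-presenting compartment did. Genes of dendritic cell maturation rose. Ccl22, a chemokine of mature dendritic cells, averaged 9.65 ± 0.42 in primed and 6.88 ± 0.46 in unimmunised arrays (SD, n = 3), a 6.85-fold rise (SE 0.34 log2, adjusted p = 6.5e-05). The costimulatory receptor Cd40 rose 3.35-fold, from 7.79 ± 0.19 to 9.53 ± 0.25 (SD, n = 3, adjusted p = 0.00012), and the actin bundler Fscn1 rose by 1.26. Of 17 maturation genes 11 rose and none fell, or 11 and 1 adjusted over the list alone (median 1.0, adjusted p = 0.0026, and adjusted p = 0.40 with an estimated correlation). Of 10 MHC class II presentation genes 8 rose, or 8 with 1 lower adjusted over the list alone, including Ciita, the master regulator of class II, by 1.55 (adjusted p = 0.0011, and adjusted p = 0.26 with an estimated correlation). Markers of dendritic cell subsets rose. Cd8a and Xcr1 of the cross-presenting cDC1 subset rose by 2.41 and 2.27, Mgl2 of the cDC2 subset by 2.31, and Spib of plasmacytoid cells by 1.85. Called were 8 of 9 cDC1 genes, 5 of 7 cDC2 genes and 6 of 7 plasmacytoid genes as higher and 1 of each as lower, with adjusted p = 0.00016, 0.048 and 0.00088, and adjusted p = 0.25, 0.26 and 0.25 with an estimated correlation. The growth factor receptor Flt3, needed for dendritic cell development, rose from 6.75 ± 0.08 to 8.41 ± 0.08 (SD, n = 3, adjusted p = 1.8e-06), and 9 of 10 dendritic cell markers rose (median 0.87, adjusted p = 0.00013, and adjusted p = 0.25 with an estimated correlation). Macrophage genes fell, 9 of 12 with 2 higher (median -0.89), and 5 of 6 red pulp macrophage genes fell, led by their lineage factor Spic, from 10.73 ± 0.13 to 9.56 ± 0.13 (SD, n = 3, adjusted p = 0.00035), each list with adjusted p = 0.00088 and with adjusted p = 0.26 with an estimated correlation. Neutrophil genes rose, 10 of 11 (median 2.38, adjusted p = 0.00013, and adjusted p = 0.26 with an estimated correlation), with the granule gene Lcn2 at 9.90 ± 0.20 against 5.32 ± 0.93 (SD, n = 3, adjusted p = 2.2e-05). These subset and cell marker counts were the same adjusted over each list alone. T cell genes rose, 5 of 9, or 6 adjusted over the list alone (median 0.61, adjusted p = 0.019, and adjusted p = 0.40 with an estimated correlation). Glycolysis genes rose, 9 of 13, also adjusted over the list alone (adjusted p = 0.0011, and adjusted p = 0.26 with an estimated correlation), with the glucose transporter Slc2a3 up 2.88-fold. Interferon response genes fell, 10 of 20, or 11 with 2 higher adjusted over the list alone (median -0.43, adjusted p = 0.00018, and adjusted p = 0.26 with an estimated correlation), with Ifit3 at -1.34.

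In that comparison limma called 3941 of 10203 genes, 2598 higher and 1343 lower, and 51.2% did not overlap against 10% by chance. Higher genes made up 65.9% of the calls, and 54.4% when the values were quantile normalized again. The groups also differed in Eif2s3y, by 6.0, and Xist, by -6.93. With the Eif2s3y level as a covariate limma called 0 genes, with 397 at an unadjusted p under 0.05, and the sign of the Xist difference turned. Eif2s3y ran from 8.533 to 8.638 in primed and from 2.464 to 2.693 in unimmunised arrays, so this covariate was nearly the group itself. The loss of calls was therefore fixed in advance and does not show that sex accounts for the change.

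Oral tolerance was set against no immunisation in CD11c+ cells, where the arrays of both groups were Xist-high. Genes of maturation and inflammation rose. Ccl22 rose 9.01-fold (adjusted p = 1.2e-05) and the chemokine Cxcl9, induced by interferon gamma, 9.26-fold, from 6.65 ± 0.44 to 9.86 ± 0.40 (SD, n = 3, adjusted p = 5.8e-07). The inhibitory ligands Pdcd1lg2 and Cd274 (PD-L2 and PD-L1) rose by 2.05 and 0.86. Of 17 maturation genes 12 rose and 2 fell, also adjusted over the list alone (median 1.22, adjusted p = 0.0099, and adjusted p = 0.46 with an estimated correlation). Of 13 glycolysis genes 12 rose, also adjusted over the list alone, with hexokinase Hk1 and pyruvate kinase Pkm up by 1.61 and 0.91 (adjusted p = 0.00016, and adjusted p = 0.34 with an estimated correlation). The acute phase gene Saa3 rose 31.6-fold, from 4.40 ± 0.71 to 9.39 ± 0.44 (SD, n = 3, adjusted p = 5.1e-06), and the complement factor Cfb rose by 3.92. Of 11 neutrophil genes 10 rose (median 2.56, adjusted p = 0.00016, and adjusted p = 0.34 with an estimated correlation), and 5 of 6 red pulp macrophage genes fell (median -1.59, adjusted p = 0.00016, and adjusted p = 0.34 with an estimated correlation), both also adjusted over the list alone, with Spic and the haem oxygenase Hmox1 at -1.93 and -1.60. Macrophage genes fell, 9 of 12 with 2 higher, or 9 and 3 adjusted over the list alone (median -1.23, adjusted p = 0.0012, and adjusted p = 0.34 with an estimated correlation). Dendritic cell and cDC1 genes rose, 8 of 10 and 8 of 9 with 1 cDC1 gene lower (medians 0.56 and 0.89, adjusted p = 0.0097 and 0.0044, and adjusted p = 0.34 for both with an estimated correlation). T cell and natural killer cell genes rose, 7 of 9 and 4 of 6, and 2 of 3 B cell genes fell (medians 0.99, 0.93 and -0.34), with adjusted p = 0.031, 0.0497 and 0.045, and adjusted p = 0.43, 0.36 and 0.34 with an estimated correlation. The counts of these last 5 lists were the same adjusted over the list alone. Of 10203 genes limma called 4958, 3252 higher and 1706 lower (56.7% higher when quantile normalized again, 65.6% otherwise), and 52.0% did not overlap against 10% by chance.

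The direct comparison of tolerised with primed CD11c+ cells called fewer genes. Saa3 was 10.6-fold higher in tolerised arrays, at 9.39 ± 0.44 against 5.98 ± 0.97 (SD, n = 3, adjusted p = 0.003), and the cystatin gene Stfa3 of myeloid cells was higher by 2.95, from 5.79 ± 0.22 to 8.74 ± 0.26 (SD, n = 3, adjusted p = 6.9e-05). Cfb was higher by 1.97 and Cxcl9 2.43-fold. The lectin gene Cd209d was lower by a log2 difference of -1.55, and Tcf4, the factor of plasmacytoid dendritic cells, by -0.66. Plasmacytoid genes fell, 3 of 7, or 5 adjusted over the list alone (median -0.58, adjusted p = 8.8e-06, and adjusted p = 0.077 with an estimated correlation). The cDC2 genes fell, 2 of 7, or 5 adjusted over the list alone (median -0.38, adjusted p = 0.00039, and adjusted p = 0.077 with an estimated correlation). Interferon response genes were higher, 3 of 20, or 9 adjusted over the list alone (median 0.26, adjusted p = 0.00039, and adjusted p = 0.32 with an estimated correlation). No maturation gene was called, with 1 higher and 1 lower adjusted over the list alone (median 0.16, adjusted p = 0.45), and the neutrophil list did not pass its test (adjusted p = 0.33). Natural killer cell genes were higher, 1 of 6, or 4 adjusted over the list alone (median 0.44, adjusted p = 0.0020, and adjusted p = 0.32 with an estimated correlation). Red pulp macrophage genes were lower, 1 of 6, or 4 adjusted over the list alone (median -0.52, adjusted p = 0.00049, and adjusted p = 0.34 with an estimated correlation). The macrophage list shifted lower with none of 12 called, or 2 higher and 3 lower adjusted over the list alone, and the dendritic cell list with 1 of 10 lower, also adjusted over the list alone (medians -0.29 and -0.094, adjusted p = 0.034 for both, and adjusted p = 0.48 and 0.45 with an estimated correlation). Eif2s3y was lower by a log2 difference of -5.97 and Xist higher by 6.61. In this comparison limma called 290 of 10203 genes, 142 higher and 148 lower, with 1825 at an unadjusted p under 0.05, and 22.9% did not overlap against 10% by chance. The count was 186 or 149 without tolerised replicate 1 or 3, and 106, 76 or 190 without primed replicate 1, 2 or 3. It was 110 with only the arrays of the 2 groups and 0 with the Eif2s3y level as a covariate, with 850 then at an unadjusted p under 0.05 and the sign of the Xist difference turned. Eif2s3y was nearly set by the group here too, so that loss of calls does not show that sex accounts for the change.

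Abatacept was compared with control IgG in these mixed CD11c+ fractions. Maturation genes fell. Ccl22 averaged 6.83 ± 0.18 under abatacept and 9.88 ± 0.68 under control IgG (SD, n = 3), an 8.26-fold fall (SE 0.34 log2, adjusted p = 0.00047). Ccl17, another chemokine of mature dendritic cells, fell 9.47-fold, from 8.81 ± 0.91 to 5.57 ± 0.43 (SD, n = 3, adjusted p = 0.00082). Cd40 fell 3.62-fold, from 9.60 ± 0.55 to 7.74 ± 0.08 (SD, n = 3, adjusted p = 0.00084), Fscn1 2.46-fold and Pdcd1lg2 3.22-fold. Of 17 maturation genes 12 fell and 1 rose, or 13 and 1 adjusted over the list alone (median -1.03, adjusted p = 6.7e-07, and adjusted p = 0.25 with an estimated correlation). Neither of the ligands that abatacept binds was called lower. Cd80 read 5.93 ± 0.39 and 5.81 ± 0.30 (SD, n = 3, adjusted p = 0.74), with a sign that turned to -0.013 without abatacept replicate 2 and -0.044 without control IgG replicate 2. Cd86 was higher by 0.37 (adjusted p = 0.021), a call lost without abatacept replicate 1 or 2 or control IgG replicate 1 or 3 (adjusted p = 0.082, 0.073, 0.076 and 0.11). Cd274 was lower by a log2 difference of -0.69 (adjusted p = 0.012, and 0.058 without control IgG replicate 3). Il12b, a subunit of interleukin-12, was lower at -0.49 (adjusted p = 0.036), a call lost without abatacept replicate 2 or 3 or control IgG replicate 1 or 3 (adjusted p = 0.10, 0.13, 0.15 and 0.077). Of 10 class II genes 7 fell, also adjusted over the list alone (median -0.36, adjusted p = 0.00042, and adjusted p = 0.22 with an estimated correlation), with the class II chain H2-Ab1 at -0.27 (adjusted p = 0.028), a call lost without abatacept replicate 1 or 2 or control IgG replicate 1 or 3 (adjusted p = 0.099, 0.094, 0.11 and 0.098). Interferon response genes rose, 12 of 20 with 1 lower, also adjusted over the list alone (median 0.58, adjusted p = 8.2e-08, and adjusted p = 0.18 with an estimated correlation), with Ifit3 up 2.46-fold, from 7.78 ± 0.33 to 9.07 ± 0.01 (SD, n = 3, adjusted p = 0.00062), and the antiviral gene Mx2 by 0.82.

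Markers of dendritic cells and macrophages moved in opposite directions under abatacept. Flt3 fell from 8.11 ± 0.18 to 7.29 ± 0.25 (SD, n = 3, adjusted p = 0.0021), and Itgax, the gene of CD11c itself, from 9.99 ± 0.12 to 9.62 ± 0.06 (SD, n = 3, adjusted p = 0.0069). Of 10 dendritic cell markers 7 fell, or 8 adjusted over the list alone (median -0.48, adjusted p = 2.3e-05, and adjusted p = 0.18 with an estimated correlation). The cDC1 gene Cd8a fell by 1.03, the cDC2 gene Mgl2 4.82-fold and the plasmacytoid gene Ccr9 by 0.96. Lower were 5 of 9 cDC1, 4 of 7 cDC2 and 5 of 7 plasmacytoid genes, or 6, 4 and 6 adjusted over the list alone, and 1 cDC2 gene rose, or 1 of each subset adjusted over the list alone, with adjusted p = 0.0012, 0.0070 and 0.0021, and adjusted p = 0.18, 0.18 and 0.20 with an estimated correlation. Of 12 monocyte and macrophage genes 6 rose and 2 fell, or 9 and 2 adjusted over the list alone (median 0.61, adjusted p = 0.0035, and adjusted p = 0.34 with an estimated correlation). The endotoxin coreceptor Cd14 rose 2.08-fold, while Lyz2 and the monocyte receptor Ccr2 fell by 1.01 and 0.68. Of 6 red pulp macrophage genes 2 rose, or 5 adjusted over the list alone (median 0.67, adjusted p = 0.0017, and adjusted p = 0.34 with an estimated correlation), with Spic up by 0.86 (adjusted p = 0.0089, and 0.052 without control IgG replicate 3). T cell genes shifted lower, 1 of 9 called, also adjusted over the list alone (median -0.40, adjusted p = 0.0081, and adjusted p = 0.34 with an estimated correlation), and glycolysis genes fell, 4 of 13, or 5 adjusted over the list alone (adjusted p = 0.0080, and adjusted p = 0.34 with an estimated correlation). Clu, a secreted chaperone, fell 21.7-fold, from 9.26 ± 0.77 to 4.82 ± 0.55 (SD, n = 3, adjusted p = 0.00022). In total limma called 1560 of 10203 genes, 656 higher and 904 lower, with 210 differing at least 2-fold, and 36.9% did not overlap against 10% by chance. Without 1 array the count reached 701 or 778 without abatacept replicate 1 or 2, 714 or 525 without control IgG replicate 1 or 3, and 2696 with array weights. It was 958 with the salivary gene level as a covariate, and 0 with the Eif2s3y level as a covariate, with 228 then at an unadjusted p under 0.05. With the salivary covariate the median of the 904 lower genes went from -0.59 to -0.60 and that of the 656 higher ones from 0.56 to 0.57, while their median SE grew from 0.136 to 0.160 and 0.159. With the Eif2s3y covariate the differences of Pdcd1lg2, Cd274, Il12b, Cd86, Itgax and Spic also changed sign. Eif2s3y was nearly set by the group here as well, so the lost calls and changed signs do not show that sex is the cause.

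**Figure D5:**
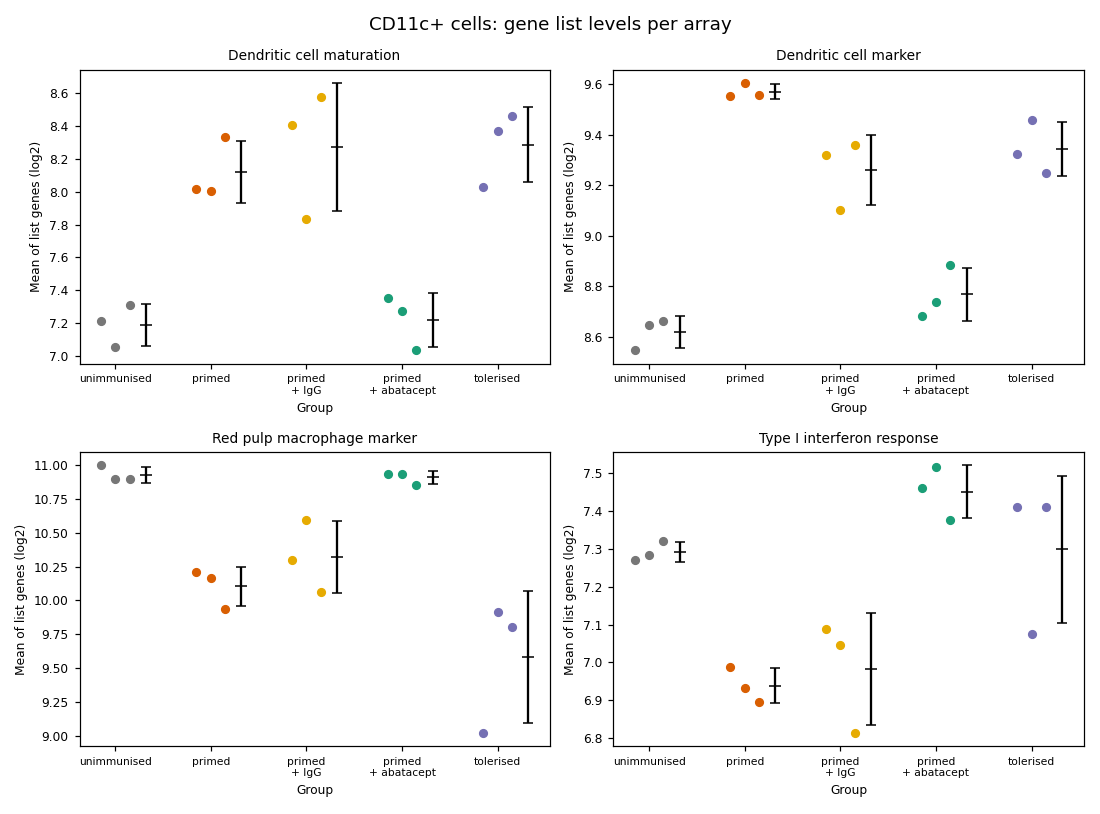
Mean log2 level of the dendritic cell maturation, dendritic cell marker, red pulp macrophage marker and type I interferon response lists in CD11c+ arrays by group, where each point is 1 array and the black bar is the mean ± SD of 3 arrays. Maturation genes averaged 7.19 in unimmunised, 8.12 in primed, 8.27 in control IgG, 7.22 in abatacept and 8.29 in tolerised arrays.

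Between control IgG and priming alone, CD11c+ cells had 2 called genes of 10203, the chitinase-like gene Chil4, which fell by 2.49 (adjusted p = 0.043), and Fndc7, which fell by 1.02 (adjusted p = 0.018). At an unadjusted p under 0.05 there were 1038 genes, and 19.8% did not overlap against 10% by chance. Without control IgG replicate 2 or 3, or without any 1 primed replicate, limma called 0 genes, and without control IgG replicate 1 the Chil4 call was lost (adjusted p = 0.22). With the Eif2s3y or the salivary gene level as a covariate it also called 0, with 714 and 607 at an unadjusted p under 0.05. With only the arrays of the 2 groups it called 50, and with array weights 150. Neutrophil genes shifted lower as a list (median -1.20, adjusted p = 5.8e-14, and adjusted p = 0.11 with an estimated correlation), with 9 of 11 lower adjusted over the list alone and none over all genes. Dendritic cell markers did likewise (median -0.28, adjusted p = 2.2e-06, and adjusted p = 0.11 with an estimated correlation), with 4 of 10 lower adjusted over the list alone. The cDC1 list also shifted lower, with 5 of 9 lower adjusted over the list alone, and the macrophage list higher, with none of 12 called either way (medians -0.33 and 0.26, adjusted p = 5.7e-05 and 0.0011, and adjusted p = 0.11 and 0.47 with an estimated correlation). Class II genes shifted lower too, none of 10 called, or 4 adjusted over the list alone (median -0.17, adjusted p = 0.0011, and adjusted p = 0.43 with an estimated correlation).

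Against tolerised mice, CD11c+ cells under abatacept were lower in maturation genes, in arrays that were Xist-high in both groups. Ccl22 and Ccl17 were 9.29-fold and 12.2-fold lower (adjusted p = 2.1e-05 and 2.7e-05), and Cd40 and Cxcl9 were lower by log2 differences of -1.95 and -2.61. Of 17 maturation genes 12 fell and 2 rose, also adjusted over the list alone (median -1.17, adjusted p = 0.00084, and adjusted p = 0.38 with an estimated correlation). Dendritic cell markers fell, 7 of 10, also adjusted over the list alone (median -0.62, adjusted p = 0.00084, and adjusted p = 0.35 with an estimated correlation). All 6 red pulp macrophage genes were higher, also adjusted over the list alone (median 1.56, adjusted p = 0.00014, and adjusted p = 0.35 with an estimated correlation), with Hmox1 at 11.66 ± 0.12 against 10.06 ± 0.47 (SD, n = 3). Saa3 was lower, at 4.98 ± 0.35 against 9.39 ± 0.44 (SD, n = 3, adjusted p = 2.1e-05), and neutrophil genes fell, 10 of 11, or 11 adjusted over the list alone (median -1.90, adjusted p = 0.00014, and adjusted p = 0.36 with an estimated correlation). Macrophage genes were higher, 9 of 12 with 2 lower (median 1.30, adjusted p = 0.00045, and adjusted p = 0.35 with an estimated correlation). The cDC1, natural killer and T cell genes were lower, 7 of 9 with 1 higher, 4 of 6 and 5 of 9 (medians -0.48, -0.60 and -0.43), with adjusted p = 0.0042, 0.029 and 0.022, and adjusted p = 0.35, 0.38 and 0.40 with an estimated correlation. The counts of these 4 lists were the same adjusted over the list alone. The reductase gene Cbr2 was 16.2-fold higher under abatacept, at 8.10 ± 0.29 against 4.08 ± 0.46 (SD, n = 3, adjusted p = 3.6e-06). Of 10203 genes limma called 3824, 1690 higher and 2134 lower, 3740 with the Eif2s3y level as a covariate, and 47.5% did not overlap against 10% by chance.

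CD11c+ cells under abatacept were set against those of unimmunised mice, both Xist-high groups. Plasmacytoid genes were higher, 4 of 7, or 6 adjusted over the list alone (median 0.67, adjusted p = 4.3e-06, and adjusted p = 0.13 with an estimated correlation), with Spib up 2.18-fold and Pacsin1 3.06-fold. Neutrophil genes were higher as well, 1 of 11, or 6 adjusted over the list alone (median 0.84), and cDC1 genes, 2 of 9, or 4 adjusted over the list alone (median 0.25), both with adjusted p = 0.021, and adjusted p = 0.69 and 0.41 with an estimated correlation. The immunoglobulin segment Igkj1 was 4.67-fold higher, at 7.78 ± 0.17 against 5.56 ± 0.19 (SD, n = 3, adjusted p = 1e-05). No maturation gene was called (median 0.05, adjusted p = 0.55). In this comparison limma called 239 of 10203 genes, 214 higher and 25 lower, with 1852 at an unadjusted p under 0.05, and 22.0% did not overlap against 10% by chance. The count was 128, 54 or 72 without abatacept replicate 1, 2 or 3, and 84 without unimmunised replicate 2. It was 91 with only the arrays of the 2 groups, 139 when quantile normalized again, and 143 with the salivary gene level as a covariate.

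Genes that priming had changed were followed under abatacept, in arrays the 2 comparisons do not share. These lists were chosen on arrays of this study. In CD11c+ cells the 2598 genes higher after priming had a median log2 difference of -0.25 between abatacept and control IgG, and 823 of them fell and 2 rose, where independent lists would give 230 and 167. The 1343 genes lower after priming had a median of 0.37, with 551 risen and 0 fallen, where independent lists would give 86.3 and 119. By camera these shifts had adjusted p = 1.1e-59 and 1.3e-66, and adjusted p = 0.0085 and 0.015 with an estimated correlation. Across genes, which are not independent replicates, the changes under priming and under abatacept correlated at r = -0.681 (rho = -0.774). Primed arrays were Y-high and unimmunised ones Xist-high, and abatacept and control IgG differed in the same transcripts. The 2403 CD4+ genes higher and 2493 lower after priming did not pass the camera test (medians -0.071 and -0.089, adjusted p = 0.83 and 0.52). Across genes r was -0.103 and rho 0.025. Tissue and other cells also shaped these lists, so no lack of reversal is shown. The 870 CD4+ genes lower in tolerised than in primed arrays were lower under abatacept as well (median -0.25, adjusted p = 8.5e-16, and adjusted p = 0.016 with an estimated correlation), with 360 fallen where independent lists would give 116. The 644 higher ones had a median of 0.060 (adjusted p = 2.7e-06, and adjusted p = 0.41 with an estimated correlation). In CD11c+ cells the 142 genes higher and the 148 lower in tolerised than in primed arrays had medians of -0.13 and 0.27 under abatacept (adjusted p = 0.0032 and 8.6e-05, and adjusted p = 0.49 and 0.35 with an estimated correlation).

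Finally the changes of both cell types were compared in 1 fit over all arrays. The difference between primed and unimmunised arrays was not the same in CD4+ and CD11c+ cells for 4541 of 10794 genes, and that between abatacept and control IgG for 1548, which was 1015 without CD11c+ control IgG replicate 3 and 2515 with array weights. Between primed and unimmunised arrays the neutrophil list also differed, by a median of -6.54 in CD4+ and 2.38 in CD11c+ cells. Between abatacept and control IgG, Eif2s3y differed by -5.10 in CD11c+ cells and averaged 2.60 ± 0.18 and 2.51 ± 0.12 in CD4+ cells (SD, n = 3). Under abatacept, cholesterol synthesis genes differed by a median of -0.60 between CD4+ and CD11c+ cells (adjusted p = 0.00013, and adjusted p = 0.095 with an estimated correlation). Immediate early genes differed by 0.38 (adjusted p = 7.8e-07, and adjusted p = 0.021 with an estimated correlation). The interferon response was higher in both cell types and differed by 0.13 (adjusted p = 0.0076, and adjusted p = 0.41 with an estimated correlation). Glycolysis genes did not pass this test (adjusted p = 0.36), and under priming none of these 4 lists did (adjusted p between 0.50 and 0.78).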

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

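Chosen only after the result was seen were the tests of other cell types and of sex for the CD4+ unimmunised arrays, and those of a lower CD11c+ share, a larger macrophage share and the salivary covariate for CD11c+ cells, with the covariate fits. A test of the difference between CD4+ and CD11c+ cells singled out 5 results. The difference between primed and unimmunised arrays was not the same in both cell types for 4541 genes, and that between abatacept and control IgG for 1548. These are not shown to be differences in response, because other-cell transcripts changed with priming in both cell types, the neutrophil list by -6.54 in CD4+ and 2.38 in CD11c+ arrays, and sex-linked transcripts differed between abatacept and control IgG in CD11c+ arrays. The test was not run without these. Under abatacept the CD4+ minus CD11c+ difference was 0.13 for the interferon list, -0.60 for the cholesterol synthesis list and 0.38 for the immediate early list (medians, log2), with adjusted p = 0.41, 0.095 and 0.021 with an estimated correlation, so only the last call held. Of 100 drawn splits of the arrays, 2 gave as many genes as the real one for priming and 1 for abatacept, the real one included. The splits exchanged arrays between the groups of each cell type, so they stand for no change in either cell type. They do not stand for an equal change in both, so they cannot exclude chance for a difference between cell types. The highest other split gave 5131 for priming, in which every CD4+ array kept its place and every CD11c+ array was exchanged between the groups, so the CD11c+ change was turned around. It gave 789 for abatacept.

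For the 7 comparisons of each cell type, 10 splits of 6 arrays are too few for a share under 0.05. The real split was the only 1 of the 10 with as many calls each time. In CD4+ T cells the real counts were 4896 and 5114 for primed and tolerised against unimmunised, 9 for control IgG against primed and 5978 for abatacept against unimmunised, with a highest other split of 0 genes each by limma. They were 1514 for tolerised against primed, 1722 for abatacept against control IgG and 2408 for abatacept against tolerised, with a highest other of 1. In CD11c+ cells they were 3941, 290, 2, 3824 and 239 for primed against unimmunised, tolerised against primed, control IgG against primed and abatacept against tolerised and unimmunised, with a highest other of 0. They were 4958 for tolerised against unimmunised and 1560 for abatacept against control IgG, with a highest other of 1.

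The CD4+ unimmunised arrays held transcripts of red cells, neutrophils and macrophages, with the globin gene Hbb-b2 at 11.8, 12.1 and 12.1. Sex of the mice is argued against, because abatacept arrays, Xist-high and Y-low like the unimmunised ones, still differed from them by a median of -5.86 over the erythroid and neutrophil lists. Other cell types left in these preparations in spite of the negative selection may be the source, since the T cell marker list was higher in primed arrays by a median of 1.06 while the lists of other cells were lower. Spleen in the pool of the unimmunised group, against lymph node in the others, is the difference the design names, and it was not tested.

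In CD11c+ cells the calls between abatacept and control IgG met a difference in sex-linked transcripts. The 904 fallen genes had a median of -0.59, yet in tolerised (Xist-high) against primed (Y-high) arrays they differed by 0.075, and the 656 risen genes had a median of 0.56 and there differed by -0.19, which argues against sex as their whole cause. With the Eif2s3y level as a covariate the medians shrank from -0.59 to -0.15 and from 0.56 to 0.068, while the median SE grew from 0.136 to 0.400 and 0.391. Calls ended for both reasons, as Eif2s3y is nearly set by the group and its slope rests mainly on the 3 control IgG arrays. Sex of the mice, for a part of the change or all of it, and the treatment itself stay open.

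Dendritic cell markers were lower and macrophage markers higher in CD11c+ cells under abatacept. A lower share of CD11c+ cells, with every other type raised alike, is argued against by the T cell list, which differed by -0.40. Salivary tissue in the control IgG samples is argued against, because the dendritic cell list differed by -0.55 from the control IgG array with least Amy1 and by -0.46 from the others, and its median stayed at -0.48 with the salivary level as a covariate. With the Eif2s3y level as a covariate that median went to -0.019, its SE from 0.133 to 0.406 and its calls from 7 to 0, so a part that goes with sex stays open. A larger share of macrophages may contribute and cannot be told apart, as 41.2% of 17 macrophage genes were called higher and the most abundant, Slc40a1, Hmox1 and C1qc, were higher by 0.32, 0.60 and 0.52 without being called (adjusted p = 0.15, 0.065 and 0.054, limma), and an effect of abatacept on the cells themselves stays open too.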

How the results depend on the processing

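Fits with a covariate, on lymph node genes and without the CD4+ unimmunised arrays were added after seeing the data. Signal near background limits the low values, so small differences of weakly expressed genes are not resolved. Of 913 named gene results, 86 were weaker with only the 2 groups in the fit, 25 with no filter, 20 when quantile normalized again and 12 with array weights, and 21 of those with a value under the mean of all probe sets. With the Eif2s3y covariate, run on CD11c+ cells only, 203 gene results held, 143 were weaker and 42 reversed. With the salivary covariate 361 held and 30 were weaker, and without the CD4+ unimmunised arrays 220 held and 13 were weaker. Leaving out 1 array kept 4960 gene results, weakened 418 and reversed 3. On lymph node genes all 191 kept their call. Where no cause is given below, the cause was not tested.

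Counts that moved by over 1.5 times were these. With only the 2 groups compared, so fewer samples, CD4+ tolerised against primed gave 822 genes and abatacept against tolerised 1107, while CD11c+ tolerised against primed gave 110, control IgG against primed 50 and abatacept against unimmunised 91. Array weights gave 15 for CD4+ control IgG against primed, and for CD11c+ cells 532 for tolerised against primed, 2696 for abatacept against control IgG and 150 for control IgG against primed, with 2515 for the difference between cell types under abatacept. CD11c+ control IgG against primed gave 5 with no filter, 1 when quantile normalized again and 0 with the mean of all probe sets (951 at an unadjusted p under 0.05, limma), and CD11c+ abatacept against unimmunised gave 139 when quantile normalized again. The salivary covariate gave 958 for CD11c+ abatacept against control IgG, where SEs grew and medians did not shrink, 143 for abatacept against unimmunised and 0 for control IgG against primed. With the Eif2s3y covariate 0 genes were left in CD11c+ primed against unimmunised, tolerised against primed, abatacept against control IgG and control IgG against primed (397, 850, 228 and 714 at an unadjusted p under 0.05, limma), and 4881, 3740 and 194 in the other 3 comparisons. Eif2s3y was nearly set by the group in all of the former but control IgG against primed, so the loss of calls there does not show sex as the cause. With an estimated correlation 3 of the 160 list calls held. Of the genes called between tolerised and primed arrays, the shift under abatacept had adjusted p = 0.407 for CD4+ higher, 0.493 for CD11c+ higher and 0.347 for CD11c+ lower genes with an estimated correlation.

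The replicate number as a block gave 4 genes in CD11c+ control IgG against primed and moved no other count by over 1.5 times, and it weakened 19 of the 913 gene results. The numbers do not pair the samples, since same-numbered arrays had deviations that correlated between -0.230 and 0.283 across genes and no comparison had all 3 pairs over 0.1.

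Leaving out each array in turn gave these ranges of called genes. For CD4+ T cells they were 3892 to 4440 in primed against unimmunised, 4206 to 4839 in tolerised against unimmunised, 984 to 1567 in tolerised against primed, 1031 to 1917 in abatacept against control IgG, 6 to 9 in control IgG against primed, 1634 to 2710 in abatacept against tolerised and 5029 to 5736 in abatacept against unimmunised. For CD11c+ cells, in the same order, they were 3021 to 3928, 4201 to 4783, 76 to 401, 525 to 1828, 0 to 2, 3009 to 3596 and 54 to 279. For the difference between cell types they were 4052 to 4472 under priming and 1015 to 1711 under abatacept.

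Named genes changed sign as follows (log2). Dpp4 went to 0.058 in CD4+ abatacept against control IgG with the mean of all probe sets, Bcl6 to -0.030 without abatacept replicate 1 (highest 0.24), and Cd80 in CD11c+ cells to -0.013 without abatacept replicate 2 and -0.044 without control IgG replicate 2 (highest 0.35). The rest turned with the Eif2s3y covariate in CD11c+ cells, a level that the groups compared nearly set. In primed against unimmunised, Srebf2 went to -0.13, Fdps to -0.31, Ier3 to -0.10, Il12b to -0.092, Pdcd1lg2 to -0.67, Hmox1 to 0.45, Aldh1a2 to -2.56, Trat1 to -0.014, Cd79b to 0.055, C1qa to 0.12, Slc40a1 to 0.036, Pecam1 to 0.33, Kdm5d to -1.06, Xist to 1.42, Cbr2 to 0.71 and Dgki to 0.073. In tolerised against primed, Irf8 went to 0.17, Mgl2 to 0.40, Xist to -1.70, Kdm5d to 1.0 and Uty to 2.34. In abatacept against control IgG, Slc2a3 went to 0.16, Il12b to 0.081, Pdcd1lg2 to 0.26, Cd274 to 0.029, Aldh1a2 to 1.48, Ly75 to 0.043, Irf8 to 0.13, Irf4 to 0.087, Itgax to 0.0013, Cd79b to -0.096, Cd68 to -0.29, Spic to -0.026, C1qa to -0.20, Pecam1 to -0.29, Xist to -4.63, Car3 to -1.61, Rspo1 to -0.38, Cbr2 to -1.27, Kdm5d to 1.0, Stap2 to 0.034 and Cd86 to -0.11.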

Other observations

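No test in this part was chosen only after the result was seen. In CD11c+ cells, genes of class I presentation and inflammation were also higher in tolerised than in unimmunised mice. Of 7 class I genes 6 rose, also adjusted over the list alone (median 0.45, adjusted p = 0.0072, and adjusted p = 0.34 with an estimated correlation). The immunoproteasome subunit Psmb8 rose from 10.15 ± 0.12 to 10.99 ± 0.11 (SD, n = 3, adjusted p = 8.5e-06, limma), and Nlrc5, the activator of class I genes, rose 2.31-fold. Of 8 inflammatory mediators 7 rose, also adjusted over the list alone (median 0.91, adjusted p = 0.0099, and adjusted p = 0.34 with an estimated correlation), among them the interferon-induced chemokine Cxcl10 by 2.84-fold. Cholesterol synthesis genes rose, 9 of 13, or 10 higher and 1 lower adjusted over the list alone, with Sqle up 1.62-fold and Idi1 1.75-fold (list median 0.48, adjusted p = 0.031, and adjusted p = 0.35 with an estimated correlation). The list of tolerogenic dendritic cell genes did not pass its test, with 4 higher and 2 lower of 7, or 4 and 3 adjusted over the list alone (adjusted p = 0.79). Of 19 CD4+ anergy genes, not tested apart from activation genes, 5 rose and 1 fell under abatacept against control IgG, or 6 and 1 adjusted over the list alone (median 0.11, adjusted p = 0.0010, and adjusted p = 0.26 with an estimated correlation).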
